A study of Caenorhabditis elegans with 12 samples.

How the data were processed

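Whole C. elegans animals at the L4 larval stage were profiled by mRNA sequencing in 12 libraries, 2 from each of 6 groups. The groups combine 3 strains (wild-type Bristol, a metl-9 knockout called KO here, and a second metl-9 strain called mut, as the labels name it without saying what its mutation is) with 2 foods (E. coli OP50, the usual laboratory food, or Pseudomonas aeruginosa PA14, a pathogen of worms). Per the labels' protocols, animals were raised on OP50 at 20 °C, washed 3 times in M9 buffer and kept for 2 h at 20 °C on slow-killing plates seeded with either bacterium 48 h before use, held at 37 °C and moved to 20 °C 24 h before use. RNA was extracted with Trizol, mRNA was selected with oligo-dT, the second strand was made with dUTP, which marks strand, and libraries were sequenced on a DNBSEQ instrument, per the labels' protocols.

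The deposited values are whole-number counts of fragments per gene name, not normalized, made by the authors with featureCounts 1.6.3 over exons of a RefSeq annotation of ce11, per the file headers. The submitters' processing notes name the spliced aligner HISAT2 2.1.0, SAMtools 1.9 and ce11, but the folder of the counted alignments is named for Bowtie 2, an aligner without splicing, per the file headers. Which of them aligned the reads is therefore not settled, and with Bowtie 2 reads across exon junctions could be missing from the counts. The recorded featureCounts call sets paired-end counting and names no strand option, so reads of overlapping genes on opposite strands were not told apart by strand, although the kit marks it. It also names no option to count multiply mapped reads, so near-identical genes such as vit-3, vit-4 and vit-5, the hsp-16 family, histones and major sperm proteins are uncertain. Of 13894 tested genes, 3023 share exon positions with another tested gene and 1518 with a higher-expressed one. Among the genes named here, exons of acdh-1, act-4, bli-1, cdh-8, clec-3, cysl-2, ech-6, fat-5, gst-5, mthf-1, perm-2 and sodh-1 share positions with another tested gene, for cdh-8 a higher-expressed one. The tables hold 42532 gene names and no summary rows. The reference annotation used for identifiers and positions is WBcel235, whose coordinates are those of ce11, and 41433 names matched a current symbol and 966 an older one.

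Totals ran from 9877725 to 10256039 counts per library. A total of 3 counts, the floor used here, is 0.293 to 0.304 CPM, the library-scaled count used for levels. Floors cover counting error only. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 1.29 to 2.14 over genes with at least 20 counts), so each group was taken as 2 samples. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical.

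Genes passing edgeR's filterByExpr (13894 genes, 99.9% of counts) were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, all 12 libraries, a term per group) in R 4.3.3. Factors were 0.958 to 0.963 for wild type on PA14 and 0.995 to 1.02 elsewhere. The common biological coefficient of variation was 3.18%. P-values were adjusted by Benjamini-Hochberg and called below 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Gene lists fixed before the data were examined, 36 of them with at least 3 tested members, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Camera sets the members of a list against all other genes. At the preset correlation its p-values rest largely on the number and spread of genes and do not measure the spread between samples. A list of mitochondrially encoded genes was not analysed here. CPM are TMM-scaled values computed here from the deposited counts, given as mean ± SD of 2 libraries.

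The comparisons are the response to PA14 in each strain and averaged over strains, each pair of strains on each food, and differences of responses. The difference of responses between mut and KO, the alternatives without both libraries that hold clx-1 reads and without genes that differ between mut and KO on OP50, and those with a replicate block on the PA14 libraries and with the wild-type libraries split between KO and mut, were added after seeing the data. Deviations of same-numbered libraries from their group means were compared over genes of at least 5 CPM. They correlated in the 3 pairs of PA14 groups (r 0.128 to 0.211) and over 0.1 in 0 of the 12 pairs with an OP50 group, so the numbers were taken, from the values alone, to go together on PA14. Pairs of an OP50 with a PA14 group were all weakly negative (r -0.101 to -0.0149), and pairs of OP50 groups had r of 0.0114 to 0.060. Named genes followed a rule set before the data were examined. It took metl-9, up to 10 higher and 10 lower genes per comparison by size among called genes with a mean of at least 1 CPM and no overlap between groups (for the mean response the same direction in the 3 strains, for differences of responses no overlap condition), up to 4 called members per list by adjusted p (or up to 2 uncalled members as values), and genes of the infection-response, PMK-1-regulated, propionate shunt and zinc lists in any comparison. Text may name fewer, from the top of each ranking. Alternatives were median-ratio size factors, no low-count filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, only the compared groups in the fit, DESeq2 1.42.0, an estimated correlation and leaving out each library.

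The fits were tested on simulated data with 200 changed genes of at least 5 CPM, 50 for each fold, so recovery of changes in genes below 5 CPM was not measured. For KO against wild type on OP50, 40% of 1.25-fold, 90% of 1.5-fold and 98% of 2-fold changes were recovered among 13721 genes. For the mean response the shares were 80%, 100% and 100% among 13723 genes, and for the difference of responses between KO and wild type 30%, 64% and 94% among 13732 genes. Calls on unchanged genes were, in that order, 11 of 175, 11 of 201 and 9 of 153 calls. The real fits called, in the same order, 658, 4194 and 2821 genes. Recovery with so many changed genes was not measured, so the shares hold for 200 changed genes only. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.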

Results

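The expression of genes was measured in whole L4 worms of 3 strains after 2 h on OP50, the normal food, or on the pathogen PA14, with 2 libraries in each of the 6 groups. Library totals ran from 9877725 to 10256039 counts. Values are library-scaled counts (CPM) as mean ± SD of the 2 libraries of a group (n = 2), and every adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or from camera for a list. The 10 highest genes held 4.12% to 4.64% of a library's counts. On the first principal component (42.8% of the variance), the wild-type libraries on PA14 stood apart from the KO and mut libraries on PA14.

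**Figure D1:**
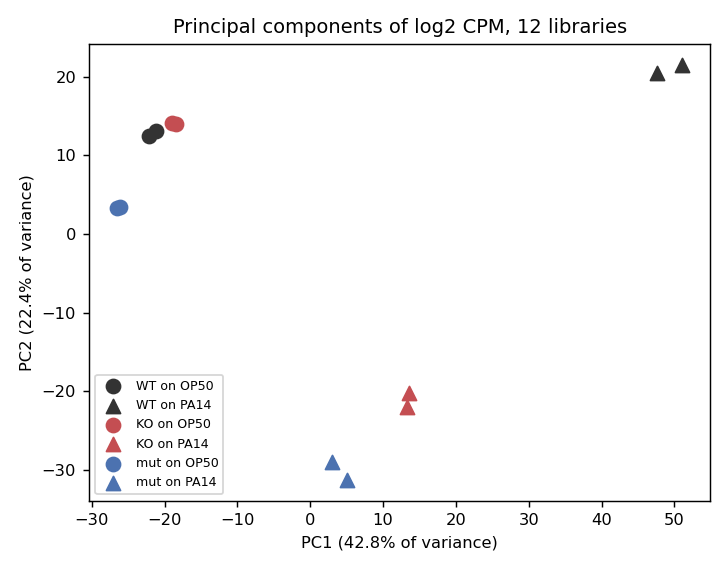
Principal components of log2 CPM over 13894 genes, with 1 point per library, circles for OP50 and triangles for PA14, coloured by strain. The wild-type libraries on PA14 lie at 51.1 and 47.6 on the first component, and KO on PA14 at 13.3 and 13.6.

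The targeted gene, metl-9 (T03G11.6, WBGene00020199, ce11 chromosome X, 5177519 to 5179213, minus strand, 6 exons in the counted annotation), was read first in every library as a check of the labels. Wild-type libraries held 19.1 and 17.5 CPM on OP50 and 20.6 and 18.4 CPM on PA14. KO libraries held 3.51 and 5.7 CPM on OP50 and 5.53 and 5.78 CPM on PA14, from 36 to 58 counts per library. Mut libraries held 19.3 and 15.1 CPM on OP50 and 19.8 and 18 CPM on PA14. In KO the gene was 3.99-fold lower than in wild type on OP50 (log2 fold change -2.0, SE 0.17, adjusted p = 1.32e-09, edgeR quasi-likelihood test). What the mutation in mut changes is not given in the labels. In mut the log2 difference of metl-9 from wild type on OP50 was -0.088 (adjusted p = 0.77), which the test did not call. Without replicate 2 of mut on OP50 this difference was 0.0768, also not called. The files sum each gene, so reads left in KO cannot be placed within it.

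Averaged over the 3 strains, PA14 raised infection-response genes and detoxification enzymes and lowered enzymes of the propionate shunt and of the methionine cycle. The CUB-like infection-response gene irg-5 (F35E12.5, chromosome V, 13737053 to 13738474) was 17.3-fold higher (log2 fold change 4.11, SE 0.028, adjusted p = 6.99e-42). The gene irg-6 (C32H11.1, chromosome IV, 12912722 to 12914969) went from 0.249 ± 0.0701 to 25.8 ± 2.91 CPM in wild type, from 0.197 ± 0.135 to 29.9 ± 1.19 in KO and from 0.145 ± 0.0682 to 35.7 ± 0.0995 in mut. Among the other genes, C32H11.4 rose 71.1-fold, F55G11.2 70.3-fold, the lectin gene clec-3 35.3-fold, the cytochrome P450 gene cyp-35D1 28.3-fold, the cadmium-responsive gene cdr-1 24-fold and the glutathione S-transferase gene gst-38 19.5-fold. The lectin gene clec-2, at 3 or fewer counts in each OP50 library, reached 19.1 ± 1.8 CPM in wild type, 2.26 ± 0.46 in KO and 2.62 ± 0.316 in mut on PA14. The acyl-CoA dehydrogenase gene acdh-1 (C55B7.4, chromosome I, 6497436 to 6499560), which starts the propionate shunt and is repressed by vitamin B12, fell 39.8-fold (log2 fold change -5.31, SE 0.15, adjusted p = 1.84e-24). For acdh-1 the log2 change was -7.05 without replicate 2 of wild type on PA14 and -7.19 without replicate 2 of both wild type and KO on PA14. Y34F4.2 went from 7.47 ± 0.0614 to 0.637 ± 0.196 CPM in KO, the transporter gene pmp-5 fell 17-fold and the fatty acid desaturase gene fat-5 14.4-fold. For fat-5 the log2 change was -4.62 without replicate 2 of both wild type and KO on PA14.

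Of the infection-response genes in the mean response, 8 rose and 0 fell of 10 tested (8 and 0 adjusted over the list alone, camera adjusted p = 7.82e-79), and of the PMK-1-regulated genes, which depend on the p38 MAP kinase of worm immunity, 16 rose and 0 fell of 17 tested (16 and 0 adjusted over the list alone, camera adjusted p = 2.78e-138). Besides irg-5, the members irg-4 (9.21-fold), irg-3 (12.3-fold) and dod-24 (7.61-fold) rose. Among glutathione S-transferases, 23 rose and 5 fell of 36 tested (24 and 5 adjusted over the list alone, camera adjusted p = 7.29e-36), with gst-5 7.15-fold and gst-7 4.36-fold higher. Of cytochromes P450, 22 rose and 13 fell of 55 tested (22 and 14 adjusted over the list alone, camera adjusted p = 3.08e-05), with cyp-35C1 5.73-fold and cyp-35A5 7.99-fold higher. In wild type alone the glutathione S-transferase list was called (camera adjusted p = 3.93e-12) and the cytochrome P450 list was not (camera adjusted p = 0.19). Of genes of fasting and lipid metabolism, 3 rose and 12 fell of 17 tested (3 and 13 adjusted over the list alone, camera adjusted p = 4.31e-22), with the carnitine transferase gene cpt-4 4.06-fold higher and the acyl-CoA synthetase gene acs-2 2.8-fold lower. For the methionine and S-adenosylmethionine cycle, 3 rose and 12 fell of 15 tested (3 and 12 adjusted over the list alone, camera adjusted p = 1.0e-63), with methionine synthase, metr-1, 4.9-fold lower and the folate enzyme gene mthf-1 2.62-fold lower. In the propionate shunt, 0 rose and 5 fell of 5 tested (0 and 5 adjusted over the list alone, camera adjusted p = 5.54e-29), with hphd-1 4.72-fold and ech-6 2.46-fold lower beside acdh-1. Of vitellogenins, the yolk proteins made in the intestine, 0 rose and 6 fell of 6 tested (0 and 6 adjusted over the list alone, camera adjusted p = 2.16e-28), and of oocyte and eggshell genes, 0 rose and 15 fell of 15 tested (0 and 15 adjusted over the list alone, camera adjusted p = 2.46e-14). By strain, the oocyte and eggshell list was called in wild type and in KO (camera adjusted p = 3.0e-04) but not in mut (camera adjusted p = 0.253). Of intestinal genes, 4 rose and 6 fell of 12 tested (5 and 6 adjusted over the list alone, camera adjusted p = 5.01e-05), with the cathepsin B-like protease genes cpr-5 2.22-fold and cpr-1 3.55-fold lower. Of genes of the hypoxia factor HIF-1 and of cyanide or sulfide handling, 4 rose and 3 fell of 9 tested (4 and 3 adjusted over the list alone, camera adjusted p = 3.08e-05). The zinc homeostasis list was not called, and 2 rose and 1 fell of 21 tested (2 and 1 adjusted over the list alone, camera adjusted p = 0.861). In all, edgeR called 2142 genes higher and 2052 lower on PA14, 228 and 249 of them by at least 2-fold, and DESeq2 called 2724. Oocyte and moulting genes moved apart between mut and KO on OP50, so counts were also made without genes that differ there, as an alternative chosen after seeing the data. These are 2302 genes, 16.6% of those tested. Comparisons that hold KO or mut on OP50 share libraries with the one that chose them, so part of the overlap is built in. Of edgeR's 4194 genes, 1282 also differ between mut and KO on OP50, and 2763 were called without such genes. Of 36 lists, 18 passed camera's test and 13 with an estimated correlation. Exons of gst-5, mthf-1, ech-6, clec-3, acdh-1 and fat-5 share positions with another tested gene, which the counting did not separate.

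In wild type, PA14 raised irg-5 from 66.2 ± 0.0155 to 3645 ± 55.9 CPM (55-fold, log2 fold change 5.78, SE 0.049, adjusted p = 5.03e-39). C32H11.4 rose 134-fold, F55G11.2 83-fold and irg-4 21.1-fold. The gene acdh-1 stood at 1087 ± 3.81 CPM on OP50 and at 0.209 and 15.9 CPM in the PA14 libraries. Yolk and oocyte genes fell in wild type. Of vitellogenins, 0 rose and 6 fell of 6 tested (0 and 6 adjusted over the list alone, camera adjusted p = 1.59e-43), with vit-2 5.99-fold and vit-6 5.07-fold lower. Of oocyte and eggshell genes, 0 rose and 15 fell of 15 tested (0 and 15 adjusted over the list alone, camera adjusted p = 2.04e-31), with the eggshell proteoglycan genes cpg-1 2.34-fold and cpg-2 2.22-fold lower. Of intestinal genes, 4 rose and 6 fell of 12 tested (5 and 6 adjusted over the list alone, camera adjusted p = 0.00217), with cpr-1 6.82-fold and cpr-5 2.93-fold lower. In the propionate shunt, 0 rose and 5 fell of 5 tested (0 and 5 adjusted over the list alone, camera adjusted p = 7.07e-25), and of fasting and lipid metabolism genes, 2 rose and 12 fell of 17 tested (2 and 12 adjusted over the list alone, camera adjusted p = 2.95e-12). For the HIF-1 and cyanide or sulfide list, 0 rose and 5 fell of 9 tested (0 and 6 adjusted over the list alone, camera adjusted p = 1.39e-04), with rhy-1 3.08-fold and the prolyl hydroxylase gene phy-2 1.66-fold lower. Of cytosolic heat-shock genes, 0 rose and 3 fell of 8 tested (0 and 3 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.0641 with an estimated correlation), with hsp-16.41 3.82-fold lower. Of infection-response genes, 9 rose and 0 fell of 10 tested (9 and 0 adjusted over the list alone, camera adjusted p = 5.6e-65), and of PMK-1-regulated genes, 16 rose and 1 fell of 17 tested (16 and 1 adjusted over the list alone, camera adjusted p = 8.69e-106). EdgeR called 2526 genes higher and 2416 lower, 376 and 661 of them by at least 2-fold, and DESeq2 called 3226. Camera called 17 of 36 lists, and 11 with an estimated correlation.

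In KO, irg-5 rose from 47.2 ± 0.931 to 481 ± 2.95 CPM (10.2-fold, log2 fold change 3.35, SE 0.050, adjusted p = 1.48e-31), F55G11.2 59.1-fold and C32H11.4 54.5-fold. The cyanoalanine synthase gene cysl-2 (K10H10.2, chromosome II, 14492826 to 14494451), which detoxifies cyanide, rose from 198 ± 3.51 to 1606 ± 34.2 CPM (8.12-fold, adjusted p = 7.38e-31). In wild type it stood at 171 ± 6.35 CPM on OP50 and 179 ± 10 on PA14. For the HIF-1 and cyanide or sulfide list in KO, 5 rose and 1 fell of 9 tested (5 and 1 adjusted over the list alone, camera adjusted p = 1.35e-22), with rhy-1 3.86-fold and cysl-1 1.71-fold higher. Of glutathione S-transferases, 23 rose and 1 fell of 36 tested (23 and 1 adjusted over the list alone, camera adjusted p = 2.16e-52), with gst-5 8.96-fold and gst-7 5.54-fold higher. Of methionine cycle genes, 1 rose and 12 fell of 15 tested (1 and 12 adjusted over the list alone, camera adjusted p = 1.67e-68), with metr-1 5.44-fold lower. Of vitellogenins, 0 rose and 6 fell of 6 tested (0 and 6 adjusted over the list alone, camera adjusted p = 2.47e-09, adjusted p = 0.0876 with an estimated correlation), with vit-1 1.86-fold lower. Of intestinal genes, 2 rose and 6 fell of 12 tested (2 and 6 adjusted over the list alone, camera adjusted p = 3.68e-05), with cpr-5 2.13-fold and cpr-1 2.72-fold lower. The gene acdh-1 fell 29.6-fold and pmp-5 19.6-fold. EdgeR called 958 genes higher and 790 lower, 244 and 171 by at least 2-fold, and DESeq2 called 1126. Of edgeR's 1748 genes, 588 also differ between mut and KO on OP50, and 1106 were called without such genes. Camera called 17 lists, and 13 with an estimated correlation.

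In mut, irg-5 rose from 54.3 ± 0.681 to 499 ± 14.7 CPM (9.19-fold, log2 fold change 3.2, SE 0.049, adjusted p = 2.7e-31), F55G11.2 70.8-fold, cyp-35D1 65.6-fold and C32H11.4 49.1-fold. The gene cysl-2 rose from 154 ± 6.91 to 1327 ± 71.2 CPM (8.59-fold), rhy-1 4.22-fold and the sulfide oxidase gene sqrd-1 2.77-fold, and for their list 6 rose and 0 fell of 9 tested (8 and 0 adjusted over the list alone, camera adjusted p = 2.44e-31). Of UDP-glucuronosyltransferases, which conjugate foreign compounds, 30 rose and 10 fell of 63 tested (34 and 11 adjusted over the list alone, camera adjusted p = 4.24e-12), with ugt-22 3.93-fold and ugt-13 4.79-fold higher. In the wild-type response that list was not called (camera adjusted p = 0.685). Of cytochromes P450, 21 rose and 6 fell of 55 tested (22 and 7 adjusted over the list alone, camera adjusted p = 2.02e-10). Of genes listed with the methionine cycle, 1 rose and 12 fell of 15 tested (1 and 12 adjusted over the list alone, camera adjusted p = 7.08e-66), with the transporter gene pmp-5 12.2-fold and mthf-1 2.72-fold lower. Of vitellogenins, 0 rose and 6 fell of 6 tested (0 and 6 adjusted over the list alone, camera adjusted p = 2.31e-08, adjusted p = 0.108 with an estimated correlation), with vit-1 1.62-fold lower. Of intestinal genes, 2 rose and 5 fell of 12 tested (3 and 5 adjusted over the list alone, camera adjusted p = 6.75e-04), with cpr-5 1.74-fold and cpr-1 2.4-fold lower. EdgeR called 892 genes higher and 712 lower, 222 and 158 by at least 2-fold, and DESeq2 called 1016. Of edgeR's 1604 genes, 569 also differ between mut and KO on OP50, and 962 were called without such genes. Camera called 18 lists, and 12 with an estimated correlation.

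**Figure D2:**
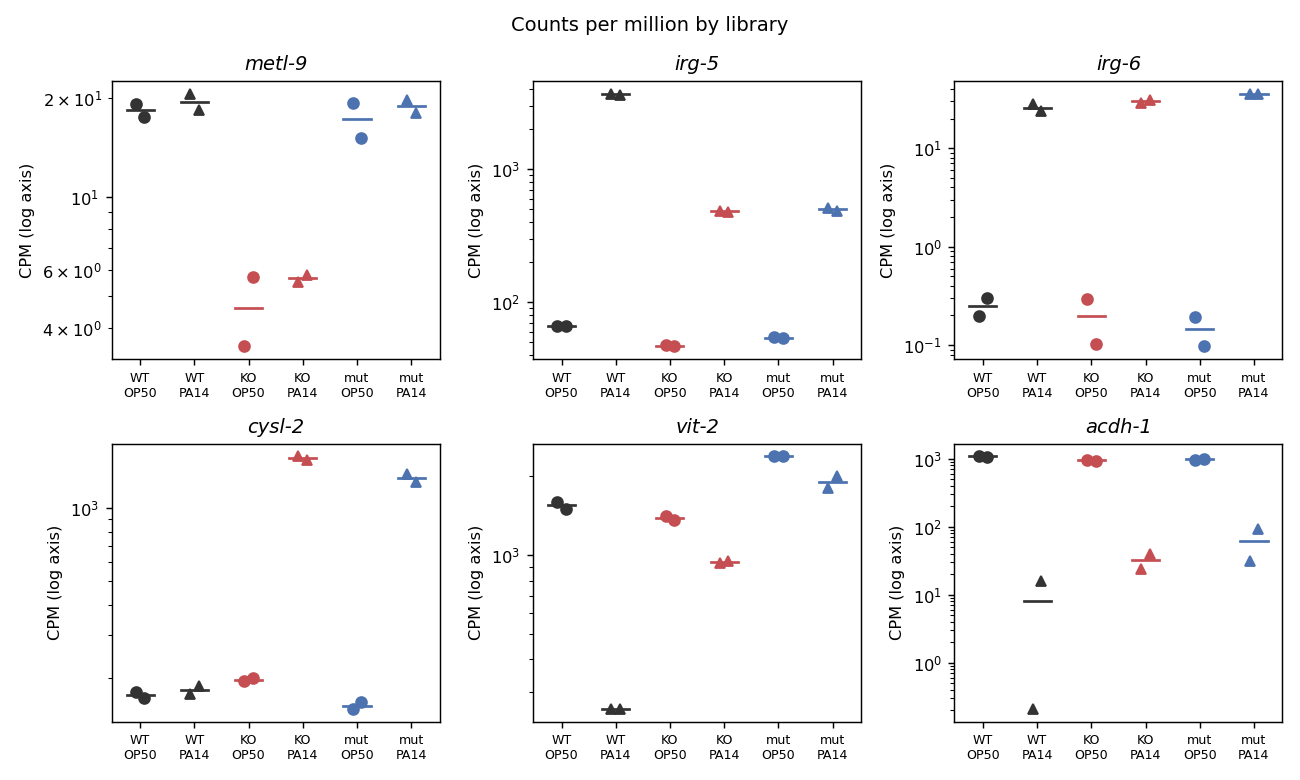
CPM (log axis) of 6 genes in each library, with 1 point per library, circles for OP50, triangles for PA14 and a bar at the group mean. On PA14, irg-5 averaged 3645 CPM in wild type, 481 in KO and 499 in mut, and cysl-2 averaged 179, 1606 and 1327.

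Whether the response to PA14 differs between KO and wild type was tested as the difference of the responses. The HIF-1 and cyanide or sulfide list was higher in the KO response, with 8 higher and 0 lower members of 9 tested (8 and 0 adjusted over the list alone, camera adjusted p = 2.08e-37). Its log2 differences were 2.95 for cysl-2, 3.57 for rhy-1 and 3.68 for sqrd-1 (adjusted p = 8.54e-14). For sqrd-1 the log2 difference was 4.48 without replicate 2 of wild type on PA14 and 4.44 without replicate 2 of both wild type and KO on PA14. The infection-response list was lower, with 0 higher and 6 lower members of 10 tested (0 and 7 adjusted over the list alone, camera adjusted p = 5.55e-09). Its members irg-5, irg-4 and irg-1 had log2 differences of -2.44 (SE 0.073, adjusted p = 7.7e-23), -1.68 and -2.23, while irg-3 reached 288 ± 2.18 CPM in wild type and 301 ± 3.03 in KO (difference 0.053, adjusted p = 0.797). For irg-3 the log2 difference was -0.0018 without replicate 2 of wild type on OP50 and -0.026 without replicate 1 of KO on OP50. PMK-1-regulated genes had 1 higher and 10 lower members of 17 tested (1 and 12 adjusted over the list alone, camera adjusted p = 3.91e-12). Vitellogenins had 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 1.6e-36). Oocyte and eggshell genes had 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 2.04e-28). The log2 differences were 1.92 for vit-6 and 2.02 for vit-2. Cytosolic heat-shock genes had 4 higher and 0 lower members of 8 tested (4 and 0 adjusted over the list alone, camera adjusted p = 8.67e-08), with hsp-16.41 at 2.4. Propionate shunt genes had 5 higher and 0 lower members of 5 tested (5 and 0 adjusted over the list alone, camera adjusted p = 8.67e-08, adjusted p = 0.117 with an estimated correlation). Body-wall muscle genes were lower in the KO response, with 0 higher and 10 lower members of 14 tested (0 and 12 adjusted over the list alone, camera adjusted p = 4.49e-07), and act-4 and mup-2 at -0.58 and -0.50. UDP-glucuronosyltransferases had 25 higher and 9 lower members of 63 tested (26 and 10 adjusted over the list alone, camera adjusted p = 2.75e-04), with ugt-13 at 2.68. K06H6.2 stood at 0.154 ± 0.218 CPM in wild type and 18.5 ± 0.49 in KO on PA14, and pud-3 had a log2 difference of -4.67. EdgeR called 1508 genes higher and 1313 lower in the KO response, and DESeq2 called 1622. Of edgeR's 2821 genes, 1093 also differ between mut and KO on OP50, and 1514 were called without such genes. Camera called 14 lists, and 9 with an estimated correlation.

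For mut against wild type, the same list of HIF-1 and cyanide or sulfide genes was higher, with 9 higher and 0 lower members of 9 tested (9 and 0 adjusted over the list alone, camera adjusted p = 1.37e-42), and log2 differences of 3.04 for cysl-2, 3.7 for rhy-1 and 3.93 for sqrd-1. For sqrd-1 the log2 difference was 4.72 without replicate 2 of wild type on PA14 and 4.72 without replicate 2 of both wild type and KO on PA14. Infection-response genes had 0 higher and 6 lower members of 10 tested (0 and 7 adjusted over the list alone, camera adjusted p = 1.88e-11), with irg-5 at -2.58 (adjusted p = 7.52e-24), irg-4 at -1.9 and irg-1 at -2.3, and PMK-1-regulated genes 1 higher and 10 lower members of 17 tested (1 and 11 adjusted over the list alone, camera adjusted p = 1.58e-15). Vitellogenins had 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 1.47e-41) and oocyte and eggshell genes 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 9.96e-42), with vit-2 at 2.26 and cpg-1 at 1.27. Genes of B12-dependent propionate breakdown were higher, with 5 higher and 0 lower members of 6 tested (5 and 0 adjusted over the list alone, camera adjusted p = 2.4e-09), and mmaa-1 at 1.03 and the mutase gene mmcm-1 at 0.75. The lectin-domain gene Y39G8B.7 was lower at -4.3, and pud-3 at -4.13. For Y39G8B.7 the log2 difference was -4.93 without replicate 1 of mut on PA14. EdgeR called 1505 genes higher and 1234 lower, and DESeq2 called 1558. Of edgeR's 2739 genes, 1029 also differ between mut and KO on OP50, and 1521 were called without such genes. Camera called 12 lists, and 9 with an estimated correlation. Between mut and KO, a comparison added after seeing the data, 32 genes were higher and 10 lower in the mut response, among them nlp-34 at 1.38 and B0024.4 at -0.83. The call on nlp-34 was lost without replicate 2 of KO on OP50 (log2 difference 1.27), replicate 2 of KO on PA14 (log2 difference 1.15), replicate 2 of mut on OP50 (log2 difference 1.24), replicate 1 of mut on PA14 (log2 difference 0.99) or replicate 2 of both wild type and KO on PA14 (log2 difference 1.14). DESeq2 called 23, the count without a low-count filter was 86, 99 genes were called with a replicate block on the PA14 libraries, and edgeR called 20 without replicate 2 of KO on OP50, 25 without replicate 2 of KO on PA14, 24 without replicate 1 of mut on OP50 and 26 without replicate 2 of mut on OP50. Of edgeR's 42 genes, 33 also differ between mut and KO on OP50, and 5 were called without such genes. Without replicate 1 of KO on OP50, 5 lists were called. Of the 10 lists called with all libraries, 0 passed with an estimated correlation.

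**Figure D3:**
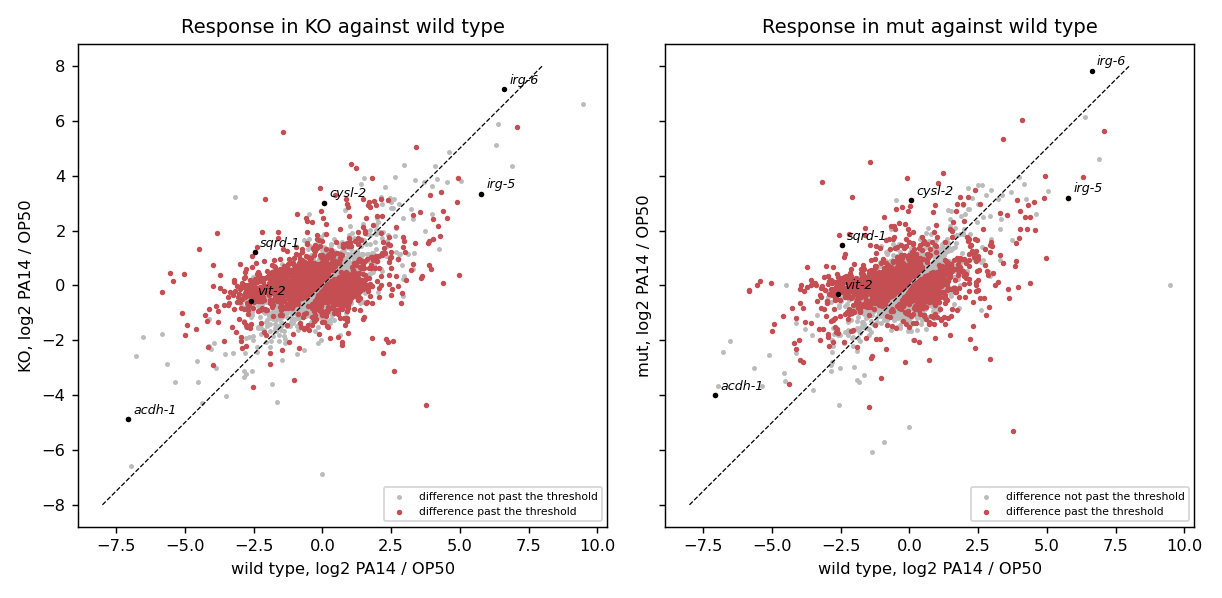
Log2 fold change on PA14 against OP50 for each gene in wild type (horizontal) and in KO or mut (vertical), with genes past the threshold for the difference in red and a dashed line of equal response. The gene irg-5 lies below the line and cysl-2 and sqrd-1 above it in both panels.

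**Figure D4:**
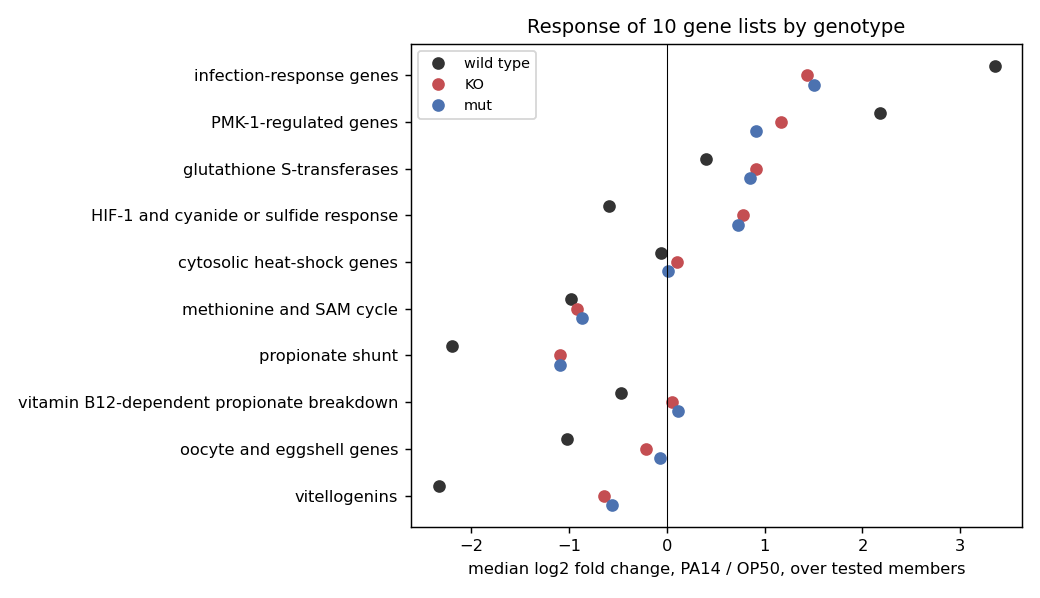
Median log2 fold change on PA14 against OP50 over the tested members of 10 gene lists, with 1 point per strain. For the HIF-1 and cyanide or sulfide list the medians are -0.59 in wild type, 0.78 in KO and 0.73 in mut.

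On OP50, moulting genes were higher in KO than in wild type, with 10 higher and 1 lower members of 21 tested (13 and 1 adjusted over the list alone, camera adjusted p = 9.7e-20), and noah-1 1.39-fold and bli-1 1.32-fold higher. Cuticle collagens were lower as a list, with 8 higher and 41 lower members of 117 tested (13 and 53 adjusted over the list alone, camera adjusted p = 2.37e-13, adjusted p = 0.334 with an estimated correlation), and col-176 1.89-fold higher and col-129 1.28-fold lower. Cytosolic heat-shock genes were higher, with 4 higher and 0 lower members of 8 tested (4 and 0 adjusted over the list alone, camera adjusted p = 1.81e-12), and hsp-70 1.6-fold and hsp-16.41 1.58-fold higher. Oocyte and eggshell genes were lower, with 0 higher and 6 lower members of 15 tested (0 and 13 adjusted over the list alone, camera adjusted p = 4.62e-12), and perm-2 1.31-fold lower. Sperm genes had 0 higher and 8 lower members of 52 tested (0 and 19 adjusted over the list alone, camera adjusted p = 1.81e-12, adjusted p = 0.363 with an estimated correlation). After metl-9, cdh-8, a cadherin gene whose exons share positions with another gene, was 2.57-fold lower, and F59B2.12 was 4.26-fold higher (adjusted p = 0.00192). The call on F59B2.12 was lost without replicate 1 of wild type on OP50 (log2 difference 1.88). The call on perm-2 was lost without replicate 1 of KO on OP50 (log2 difference -0.28). EdgeR called 308 genes higher and 350 lower, 17 and 10 by at least 2-fold, DESeq2 called 337, and edgeR called 258 without replicate 1 of wild type on OP50, 269 without replicate 2 of wild type on OP50, 270 without replicate 1 of KO on OP50 and 424 without replicate 2 of KO on OP50. Of edgeR's 658 genes, 492 also differ between mut and KO on OP50, a comparison that shares the KO libraries, and 54 were called without such genes. Camera called 9 lists, and 4 with an estimated correlation.

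In mut on OP50, oocyte and eggshell genes were higher than in wild type, with 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 1.02e-36), and cbd-1 1.35-fold higher. Vitellogenins had 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 3.85e-37), with vit-6 1.55-fold and vit-2 1.54-fold higher. Moulting genes had 1 higher and 16 lower members of 21 tested (2 and 16 adjusted over the list alone, camera adjusted p = 1.04e-29), with bli-2 1.33-fold and the timing gene lin-42 1.38-fold lower. Cuticle collagens had 56 higher and 17 lower members of 117 tested (57 and 20 adjusted over the list alone, camera adjusted p = 2.35e-19, adjusted p = 0.201 with an estimated correlation), with col-80 1.42-fold and col-20 1.38-fold higher. F40F9.3 (chromosome V, 9715209 to 9716381) was 12.1-fold higher, at 22.4 ± 0.401 against 1.84 ± 0.355 CPM (log2 fold change 3.6, SE 0.18, adjusted p = 4.66e-15). The antimicrobial peptide gene cnc-2 was 4.03-fold lower. The call on cnc-2 was lost without replicate 2 of wild type on OP50 (log2 difference -1.65), replicate 1 of mut on OP50 (log2 difference -1.86) or replicate 2 of mut on OP50 (log2 difference -2.18). EdgeR called 500 genes higher and 681 lower, 29 and 25 by at least 2-fold, DESeq2 called 595, and edgeR called 637 without replicate 1 of wild type on OP50, 654 without replicate 2 of wild type on OP50, 672 without replicate 1 of mut on OP50 and 703 without replicate 2 of mut on OP50. Of edgeR's 1181 genes, 913 also differ between mut and KO on OP50, a comparison that shares the mut libraries, and 92 were called without such genes. Camera called 15 lists, and 3 with an estimated correlation.

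Set directly against KO on OP50, mut had 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 2.44e-43) for oocyte and eggshell genes, 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 3.37e-28) for vitellogenins, 1 higher and 18 lower members of 21 tested (2 and 18 adjusted over the list alone, camera adjusted p = 9.07e-46) for moulting genes and 59 higher and 14 lower members of 117 tested (61 and 18 adjusted over the list alone, camera adjusted p = 3.28e-30, adjusted p = 0.146 with an estimated correlation) for cuticle collagens. F40F9.3 was 13.6-fold higher, puf-5 1.7-fold higher, col-20 1.76-fold higher, noah-1 1.78-fold lower and bli-1 1.69-fold lower. Antimicrobial peptide genes were lower in mut, with 0 higher and 7 lower members of 16 tested (0 and 7 adjusted over the list alone, camera adjusted p = 6.4e-04, adjusted p = 0.265 with an estimated correlation). EdgeR called 1069 genes higher and 1233 lower in mut, 86 and 60 by at least 2-fold, DESeq2 called 1261, and edgeR called 1529 without replicate 1 of mut on OP50. Camera called 15 lists, and 3 with an estimated correlation. On PA14 the same 4 lists gave 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 4.07e-66) for oocyte and eggshell genes, 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 3.28e-32) for vitellogenins, 1 higher and 18 lower members of 21 tested (1 and 18 adjusted over the list alone, camera adjusted p = 2.21e-33) for moulting genes and 52 higher and 20 lower members of 117 tested (57 and 25 adjusted over the list alone, camera adjusted p = 3.55e-27, adjusted p = 0.117 with an estimated correlation) for cuticle collagens. There F40F9.3 was 12.5-fold higher, C50F7.5 6.84-fold lower and Y46H3A.5 5.65-fold lower, and col-20 1.96-fold higher. For C50F7.5 the log2 difference was -3.46 without replicate 1 of KO on PA14, -1.5 without replicate 2 of KO on PA14 and -1.51 without replicate 2 of both wild type and KO on PA14. EdgeR called 1173 genes higher and 1274 lower, DESeq2 called 1265, and edgeR called 1579 without replicate 2 of KO on PA14. Of edgeR's 2447 genes, 1387 also differ between mut and KO on OP50, and 607 were called without such genes. Camera called 11 lists, and 4 with an estimated correlation.

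On PA14, KO held more transcripts of cyanide and sulfide handling and fewer of infection-response genes than wild type. The HIF-1 and cyanide or sulfide list had 9 higher and 0 lower members of 9 tested (9 and 0 adjusted over the list alone, camera adjusted p = 2.92e-38), with cysl-2 8.96-fold (log2 fold change 3.16, SE 0.050, adjusted p = 5.81e-31), rhy-1 9.18-fold and sqrd-1 14.7-fold higher. Infection-response genes had 0 higher and 7 lower members of 10 tested (1 and 7 adjusted over the list alone, camera adjusted p = 6.07e-19), with irg-5 7.59-fold, irg-4 3.36-fold and irg-1 4.53-fold lower, and PMK-1-regulated genes 1 higher and 14 lower members of 17 tested (2 and 14 adjusted over the list alone, camera adjusted p = 5.44e-23). Cytosolic heat-shock genes had 5 higher and 0 lower members of 8 tested (5 and 0 adjusted over the list alone, camera adjusted p = 1.57e-14), with hsp-16.41 8.32-fold higher. Vitellogenins had 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 5.0e-28) and oocyte and eggshell genes 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 4.86e-16). C-type lectins had 18 higher and 43 lower members of 106 tested (18 and 46 adjusted over the list alone, camera adjusted p = 5.44e-06), with clec-4 4.73-fold and clec-3 4.35-fold lower. Body-wall muscle genes had 0 higher and 10 lower members of 14 tested (0 and 12 adjusted over the list alone, camera adjusted p = 2.13e-05). B12-dependent propionate genes had 5 higher and 0 lower members of 6 tested (5 and 0 adjusted over the list alone, camera adjusted p = 3.3e-08), with mmcm-1 1.63-fold higher. K06H6.2 stood at 18.5 ± 0.49 CPM against 0.154 ± 0.218 and gst-19 at 16.7 ± 1.77 against 0.36 ± 0.362. The lectin-domain gene Y39G8B.7 was 17-fold lower, BE0003N10.6 14.6-fold lower and pud-3 14.2-fold lower. For sqrd-1 the log2 difference was 4.68 without replicate 2 of wild type on PA14 and 4.64 without replicate 2 of both wild type and KO on PA14. For Y39G8B.7 the log2 difference was -4.73 without replicate 2 of both wild type and KO on PA14. EdgeR called 2267 genes higher and 2194 lower, 585 and 265 by at least 2-fold, and DESeq2 called 2718. Of edgeR's 4461 genes, 1368 also differ between mut and KO on OP50, and 2916 were called without such genes. Camera called 20 lists, and 10 with an estimated correlation.

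On PA14, mut also differed from wild type in cyanide, infection-response and oocyte genes. The HIF-1 and cyanide or sulfide list had 9 higher and 0 lower members of 9 tested (9 and 0 adjusted over the list alone, camera adjusted p = 3.07e-28), with cysl-2 7.4-fold and rhy-1 11.9-fold higher. Infection-response genes had 1 higher and 9 lower members of 10 tested (1 and 9 adjusted over the list alone, camera adjusted p = 1.77e-18), with irg-5 7.31-fold and irg-1 4.4-fold lower, and PMK-1-regulated genes 2 higher and 12 lower members of 17 tested (2 and 13 adjusted over the list alone, camera adjusted p = 6.33e-22). Oocyte and eggshell genes had 15 higher and 0 lower members of 15 tested (15 and 0 adjusted over the list alone, camera adjusted p = 1.95e-59) and vitellogenins 6 higher and 0 lower members of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 1.5e-53), with vit-2 7.36-fold and cpg-1 3.1-fold higher. Y39G8B.7 was 34.2-fold lower. For Y39G8B.7 the log2 difference was -5.73 without replicate 1 of mut on PA14. EdgeR called 2538 genes higher and 2553 lower, 670 and 356 by at least 2-fold, and DESeq2 called 3329. Of edgeR's 5091 genes, 1524 also differ between mut and KO on OP50, and 3389 were called without such genes. Camera called 19 lists, and 7 with an estimated correlation.

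Across 13894 genes, which are not independent replicates, the responses to PA14 correlated between KO and mut (Pearson r = 0.745, Spearman rho = 0.425), wild type and KO (r = 0.468, rho = 0.25) and wild type and mut (r = 0.441, rho = 0.256). No library enters both sides of these correlations. Of 1037 genes called at 2-fold or more in wild type, 789 had the same sign in KO and 401 were called there the same way, and the median of the KO over the wild-type log2 change was 0.234. From KO to mut the median over 415 genes was 0.907. Genes called higher in the responses of both KO and mut numbered 651, against 61.5 for independent lists, and genes lower in both 491 against 40.5. The differences of KO and of mut from wild type share the wild-type libraries. On PA14 they correlated at r = 0.836 with a covariance of 0.314, against r = 0.523 and 0.035 in 10 simulations of unchanged groups. On OP50 they correlated at r = 0.287 with a covariance of 0.0248, against 0.503 and 0.0268, and the observed r was 0.536 without replicate 1 of wild type on OP50 and 0.519 without replicate 2 of wild type on OP50. Genes higher in both on PA14 numbered 1549, against 414 for independent lists, and genes lower in both 1616 against 403. Genes called in opposite directions numbered 58 on PA14 (32 without replicate 1 of wild type on PA14 and 31 without replicate 2 of wild type on PA14), and in the simulations 0.40 genes were called the same way in both. On OP50, 21 genes were higher in both, against 11.08 for independent lists, 60 were lower in both against 17.2, and 215 were called in opposite directions, with 0.60 called the same way in the simulations. These numbers of genes higher in both, lower in both and opposite on OP50 were 12, 25 and 90 without replicate 1 of wild type on OP50, 4, 24 and 89 without replicate 2 of wild type on OP50, 15, 31 and 121 without replicate 1 of KO on OP50, 11, 35 and 156 without replicate 1 of mut on OP50 and 12, 37 and 155 without replicate 2 of mut on OP50. In an alternative chosen after seeing the data, 1 wild-type library was set against KO and the other against mut, so that no library enters both differences. The wild-type side of each difference was then 1 library, assumed to vary like the other groups, so the numbers of genes called rest on that assumption. The low-count filter was also run again, which gave 14141 genes on PA14 and 14183 on OP50. On PA14 the correlation was then 0.592 with replicate 1 against KO and 0.679 with replicate 2 against KO (covariances 0.299 and 0.323). Genes higher in both numbered 1102 and 1123, against 277 and 266 for independent lists, and genes lower in both 1089 and 1092, against 250 and 228. On OP50 the correlation was 0.0414 and 0.0305 (covariances 0.00595 and 0.00443), with 6 and 6 genes higher in both, against 2.35 and 2.39 for independent lists, and 17 and 21 lower in both, against 3.7 and 3.48.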

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

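Every test of an explanation given here was chosen after the result was seen, and the test of wild-type RNA on OP50 was added after that on PA14. The results listed were picked out because a test of the difference between strains in the response to PA14 called them.

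Between KO and wild type, 2821 genes and 14 lists differed in the response. The log2 differences, KO minus wild type, were -0.58 for act-4, 2.95 for cysl-2, 2.4 for hsp-16.41, -2.23 for irg-1, -1.68 for irg-4, -2.44 for irg-5, -0.50 for mup-2, -4.67 for pud-3, 3.57 for rhy-1, 3.68 for sqrd-1, 2.68 for ugt-13, 2.02 for vit-2 and 1.92 for vit-6. K06H6.2, with a group at the floor and so no fold, averaged 18.5 CPM in KO on PA14. For sqrd-1 the log2 difference was 4.48 without replicate 2 of wild type on PA14 and 4.44 without replicate 2 of both wild type and KO on PA14. Between mut and wild type, 2739 genes and 12 lists differed. The log2 differences, mut minus wild type, were -4.3 for Y39G8B.7, 1.27 for cpg-1, 3.04 for cysl-2, -2.3 for irg-1, -1.9 for irg-4, -2.58 for irg-5, 1.03 for mmaa-1, 0.75 for mmcm-1, -4.13 for pud-3, 3.7 for rhy-1, 3.93 for sqrd-1 and 2.26 for vit-2. For sqrd-1 the log2 difference was 4.72 without replicate 2 of wild type on PA14 and 4.72 without replicate 2 of both wild type and KO on PA14. For Y39G8B.7 the log2 difference was -4.93 without replicate 1 of mut on PA14. Between mut and KO, 42 genes and 10 lists differed, with -0.83 for B0024.4 and 1.38 for nlp-34. The call on nlp-34 was lost without replicate 2 of KO on OP50 (log2 difference 1.27), replicate 2 of KO on PA14 (log2 difference 1.15), replicate 2 of mut on OP50 (log2 difference 1.24), replicate 1 of mut on PA14 (log2 difference 0.99) or replicate 2 of both wild type and KO on PA14 (log2 difference 1.14).

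The first pattern is that the response to PA14 in wild type differed from that in both KO and mut, whose mutation the labels do not give. A scaling error moves the log2 difference of every gene by 1 constant, and the tables argue against it, because in the difference between KO and wild type 2821 genes were called with no shift and 2801 at the constant that left the fewest, among log2 shifts of up to 3 either way, with 2697 genes called in both. Developmental stage may contribute and stays open. Of the squared KO minus wild-type change on PA14, 7.79% lay along the mut minus KO difference on OP50, in which oocyte and moulting genes moved apart, but that axis is an assumed profile of stage and bounds nothing. Plate, lawn or culture cannot be told apart from the groups. The titles of 0 libraries name one, and the plate settings in the protocols are the same for all samples. An effect of metl-9 is likewise untested.

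The second pattern is 6 genes, chosen after their values were seen, with at least 5 CPM in replicate 2 of both wild type and KO on PA14 and over 1.5-fold above both first replicates, which are clx-1, C50F7.5, asns-2, mtl-1, clec-70 and F42A10.7, with clx-1 at 17.8 and 22.3 CPM against 0 and 0 in the first replicates and at most 0.102 CPM in the other 10 libraries. Mixing with the other 10 libraries is argued against for 3 of the 6 genes (clx-1, C50F7.5 and asns-2), which lay over 1.2-fold above the highest of those libraries, and mixing with any single library for the set, because the 6 genes would need a median share of at least 91.4% and in 0 of the 22 pairs of receiving and source library did the other genes allow the share needed (18.1% allowed for KO into wild type on PA14). OP50 RNA in the wild-type library would need a median share of 36.1% over 9 genes other than acdh-1 that were higher in replicate 2. Because acdh-1 allows 1.45%, this argues against OP50 RNA as the source of those 9 genes. A share of up to 1.45% stays possible, and it would account for acdh-1 itself, at 0.209 CPM in replicate 1 and 15.9 in replicate 2. A day shared by the second replicates of all 6 groups and acting the same way on both foods is argued against. The reason is that 0 of the 12 pairs of groups with an OP50 group have replicate deviations that correlate over 0.1 (highest r 0.060). Pairs of an OP50 with a PA14 group were all weakly negative (r -0.101 to -0.0149), so a day acting in opposite ways on the foods was not addressed. A day, plate or lawn shared by the second replicates on PA14 stays open, because 3 of the 3 pairs of PA14 groups correlate over 0.1, no label says what they share, and replicate 2 of mut on PA14 held 0 CPM of clx-1 but 92.7 CPM of acdh-1 against 31.2 in replicate 1, and RNA from outside the series was not tested.

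The third pattern is the metl-9 reads left in the KO libraries. RNA of wild type on PA14 in the KO libraries on PA14 would need a share of at least 26.8%. Below that share lay 18 genes, irg-5 among them at 13.4%, which argues against this source there. RNA of wild type on OP50 was not tested in those libraries. For KO on OP50, set against wild type on OP50, the needed share was 18.3% and 0 genes lay below it. There 1 gene of at least 10 CPM besides metl-9 was lower by 2-fold or more, so the test could not decide. Exons outside the deleted part may give the reads, and this stays open, because the 6 exons are summed in the files.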

How the results depend on the processing

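The alternatives without both libraries with clx-1 reads, without genes that differ between mut and KO on OP50, with a replicate block on the PA14 libraries and with split controls, and all values for the difference of responses between mut and KO, were chosen after seeing the data, and all others before the data were examined. Median-ratio scaling and a fit of only the compared groups kept each count of genes and of lists within 1.5 times its main value. DESeq2 called fewer genes, and the cause was not tested: 2724 (response, mean of the 3 genotypes), 3226 (response in wild type), 1126 (response in KO), 1016 (response in mut), 337 (KO against wild type on OP50), 2718 (KO against wild type on PA14), 595 (mut against wild type on OP50), 3329 (mut against wild type on PA14), 1261 (mut against KO on OP50), 1265 (mut against KO on PA14), 1622 (difference of responses, KO minus wild type), 1558 (difference of responses, mut minus wild type) and 23 (difference of responses, mut minus KO). With an estimated correlation in place of the preset 0.01, fewer lists were called, and the cause was not tested: 11 (response in wild type), 4 (KO against wild type on OP50), 10 (KO against wild type on PA14), 3 (mut against wild type on OP50), 7 (mut against wild type on PA14), 3 (mut against KO on OP50), 4 (mut against KO on PA14), 9 (difference of responses, KO minus wild type) and 0 (difference of responses, mut minus KO). Without genes that differ between mut and KO on OP50, counts fell to 2763 (response, mean of the 3 genotypes), 1106 (response in KO), 962 (response in mut), 54 (KO against wild type on OP50), 2916 (KO against wild type on PA14), 92 (mut against wild type on OP50), 3389 (mut against wild type on PA14), 607 (mut against KO on PA14), 1514 (difference of responses, KO minus wild type), 1521 (difference of responses, mut minus wild type) and 5 (difference of responses, mut minus KO). The 2302 genes left out, 16.6% of those tested, were themselves chosen for a difference between strains. They held 492 of the 658 calls between KO and wild type and 913 of the 1181 between mut and wild type on OP50, comparisons that share libraries with the one that chose them. The fit was not repeated, and the p-values of the genes kept were adjusted again among themselves. That adjustment made the rest of the fall, on OP50 from 166 to 54 calls between KO and wild type and from 268 to 92 between mut and wild type. With no low-count filter the counts rose to 17 (mut against KO on PA14) lists and 86 (difference of responses, mut minus KO) genes, and the cause was not tested. Correlations of responses between strains moved with a filter of 1 CPM in 4 libraries to 0.497 (WT and KO), 0.484 (WT and mut) and 0.778 (KO and mut), and without both clx-1 libraries to 0.386 (WT and KO), 0.415 (WT and mut) and 0.685 (KO and mut), and the cause was not tested. With split controls, which by construction share no library, the correlation of the KO and mut differences from wild type fell to 0.592 and 0.679 on PA14 and 0.0414 and 0.0305 on OP50. The low-count filter was run again there, giving 14141 genes on PA14 and 14183 on OP50 against 13894, so the fall mixes both changes.

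Leaving out each library in turn, with the lone library of a group assumed to vary like the other groups, gave counts of called genes of 3746 to 4082 (response, mean of the 3 genotypes), 3814 to 5064 (response in wild type), 1316 to 1805 (response in KO), 1179 to 1650 (response in mut), 258 to 736 (KO against wild type on OP50), 3321 to 4529 (KO against wild type on PA14), 637 to 1245 (mut against wild type on OP50), 4089 to 5204 (mut against wild type on PA14), 1529 to 2406 (mut against KO on OP50), 1579 to 2523 (mut against KO on PA14), 2222 to 2884 (difference of responses, KO minus wild type), 2136 to 2828 (difference of responses, mut minus wild type) and 20 to 62 (difference of responses, mut minus KO). List counts were 17 to 20 (response, mean of the 3 genotypes), 16 to 19 (response in wild type), 16 to 19 (response in KO), 18 to 19 (response in mut), 8 to 10 (KO against wild type on OP50), 17 to 21 (KO against wild type on PA14), 10 to 15 (mut against wild type on OP50), 18 to 19 (mut against wild type on PA14), 13 to 16 (mut against KO on OP50), 11 to 15 (mut against KO on PA14), 13 to 14 (difference of responses, KO minus wild type), 12 to 14 (difference of responses, mut minus wild type) and 5 to 15 (difference of responses, mut minus KO). Correlations were 0.385 to 0.442 (agreement of responses between genotypes: WT and KO), 0.378 to 0.427 (agreement of responses between genotypes: WT and mut), 0.638 to 0.708 (agreement of responses between genotypes: KO and mut), 0.262 to 0.536 (differences from wild type on OP50) and 0.764 to 0.863 (differences from wild type on PA14). The low-count filter was run again in each of these fits, with a group of 1 library. These ranges therefore mix a change of the genes kept with the loss of a library. The log2 difference of metl-9 between mut and wild type on OP50, not called, changed sign to 0.0768 without replicate 2 of mut on OP50 (range -0.275 to 0.0768), and that of irg-3 in the difference of responses between KO and wild type, also not called, ranged from -0.0263 to 0.148.

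The labels give all groups replicate numbers 1 and 2 and do not say what a number marks. With a replicate block over all libraries, 4155 genes were called in the mean response and 657 between KO and wild type on OP50, and no count moved by over 1.5 times. Same-numbered libraries deviated together on PA14 and not across all groups, and with a replicate block on the PA14 libraries alone 99 genes differed in response between mut and KO in place of 42, and the cause was not tested. No other count moved by over 1.5 times, no named gene changed its call, and 13 of 468 list tests did, none of them one described in the report. At this depth, folds are not given for genes with a group at or below 3 counts per library.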

Other observations

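The test of a weaker response and the counts of splits were chosen after the results were seen. Genes of the endoplasmic reticulum stress response rose on PA14 in the mean response, where 7 rose and 0 fell of 8 tested (7 and 0 adjusted over the list alone, camera adjusted p = 3.86e-05, adjusted p = 0.0555 with an estimated correlation), with the chaperone gene hsp-4 1.47-fold higher. Of antioxidant genes, 4 rose and 1 fell of 13 tested (4 and 1 adjusted over the list alone, camera adjusted p = 6.25e-05), with gst-4 6.13-fold higher. Of genes regulated by the insulin-pathway factor DAF-16, 0 rose and 5 fell of 10 tested (0 and 6 adjusted over the list alone, camera adjusted p = 9.79e-05, adjusted p = 0.151 with an estimated correlation), with sodh-1 2.45-fold lower. Cytosolic ribosomal protein genes rose in wild type, where 66 rose and 0 fell of 78 tested (67 and 0 adjusted over the list alone, camera adjusted p = 2.24e-05, adjusted p = 0.611 with an estimated correlation). In mut against KO on PA14, germline genes had 11 higher and 0 lower members of 24 tested (12 and 0 adjusted over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.117 with an estimated correlation) and sperm genes 27 higher and 0 lower members of 52 tested (35 and 0 adjusted over the list alone, camera adjusted p = 4.08e-08, adjusted p = 0.441 with an estimated correlation). On OP50, iron and haem genes had 2 higher and 0 lower members of 15 tested (2 and 0 adjusted over the list alone, camera adjusted p = 1.72e-04) in KO against wild type, and lysozymes and saposin-like proteins 0 higher and 7 lower members of 30 tested (0 and 11 adjusted over the list alone, camera adjusted p = 8.26e-04, adjusted p = 0.201 with an estimated correlation) in mut against wild type. In KO against wild type on PA14, histone genes had 2 higher and 13 lower members of 25 tested (2 and 14 adjusted over the list alone, camera adjusted p = 0.00242, adjusted p = 0.129 with an estimated correlation). Of components of the p38 MAP kinase pathway, 5 rose and 1 fell of 9 tested (6 and 1 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.118 with an estimated correlation) in the mean response.

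Several lists were not called in any planned comparison, and their counts in the mean response follow. Of pals genes, 2 rose and 3 fell of 15 (2 and 3 adjusted over the list alone, camera adjusted p = 0.755). Of F-box A genes, 24 rose and 10 fell of 99 (24 and 10 adjusted over the list alone, camera adjusted p = 0.861). For the mitochondrial unfolded protein response, 1 rose and 2 fell of 7 (1 and 2 adjusted over the list alone, camera adjusted p = 0.861). For nuclear genes of mitochondrial complex I, 0 rose and 1 fell of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.884). Among neuronal genes, 3 rose and 0 fell of 17 (2 and 0 adjusted over the list alone, camera adjusted p = 0.55). Among FMRFamide-like neuropeptide genes, 2 rose and 2 fell of 29 (2 and 1 adjusted over the list alone, camera adjusted p = 0.939).

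A hypothesis chosen after the data were seen was that KO gives the wild-type response at a lower strength. It needs at most 5% of the genes called in both responses to go opposite ways, and 20.3% did, which argues against it.

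To ask how often other splits give the mean response, the 12 libraries were split 6 against 6 in 100 of 462 ways, with strain as a term and no strain-specific response. The real split called 2275 genes, 2 of the splits, the real one included, gave as many, and the highest other split called 3241. No label says that the 2 libraries of a group are separate cultures, and most of these splits part such libraries, so this count decides nothing about chance. With the 2 libraries of each group kept together, 3 of the 10 splits, the real one included, gave as many genes, with 2275 for the real split and 3241 for the highest other, and 10 splits are too few for a share under 0.05. The highest other split parts the wild-type libraries by food and leaves KO and mut whole, so it holds the wild-type response alone and points to a structure of the samples.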
